A study of Arabidopsis thaliana with 20 samples.

How the data were processed

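The data were 20 arrays of total RNA from Arabidopsis thaliana, 10 labelled WT and 10 labelled hcf145. Groups and array numbers came from the sample titles. The source names of the mutant samples give gun5 in place of hcf145, and this conflict was left open. The authors deposited 1 table of intensity values on a linear scale, with 3439 features and 1 column per array; the unit was read from the values, since no label names it. The column means lie near 1, no value is below 0, and the hcf145 columns stop at 100. How the authors quantified, scaled and capped the values is not given in the sources used here. Which of background subtraction, scaling and averaging of spots were applied stays unknown, and the kind of array is not given in the labels.

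Features were named through the platform's annotation table, in which 692 features had 1 gene, 870 several and 1877 none; 690 of the 692 were matched to the RefSeq gene table of assembly TAIR10.1, which was used for names only. Features with several genes were not named. Genome coordinates were not used here.

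Zeros (values at or below 0) were set missing, values were taken to log2, and features with fewer than 5 values in either group were left out, which removed 152 and left 3287. The column medians ran from 0.312 to 0.493, more than the 10% limit set beforehand, so the arrays were quantile normalised. Differences were tested with limma (version 3.58.1, in R 4.3.3; lmFit and eBayes, group as the only term, two-sided) on all 20 arrays with Benjamini-Hochberg adjustment over the features tested, at a threshold of 0.05. Fold changes are differences of mean normalised log2 values, hcf145 minus WT, and intensities are means of the deposited values. Dim features and those with zeros have less certain fold changes, because the log scale widens small differences near 0 and a zero carries no log value.

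The genes named were fixed by a rule: HCF145 and CHLH; the 12 largest rises and 12 largest falls past the threshold among features with 1 gene and at least 8 values per group; in each list up to 2 rises and 2 falls past the threshold, or the member with the smallest p; and all measured photosystem I and light-harvesting complex I genes. Genes named beyond this rule (CRR21, OTP70, OTP85, NDHS, NDHN, AT4G31530 and the members of short lists that are given beside those of the rule) were chosen after their values were seen. Gene lists were tested with camera (cameraPR on the moderated statistics, since some values are missing, with a preset correlation of 0.01) against the other single-gene features, using the brightest feature of each gene, for lists with at least 3 measured members. Adjustment was over the 10 lists tested, 2 of them fixed before the data were examined and 8 written after the gene names had been read and before any difference between the groups was computed.

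The choices made before the data were examined were the main test, the 18 fixed lists, the rule for named genes and these alternatives: the values as deposited, centring on the median of all features or of features outside the lists, leaving out the dimmest 25%, zeros at the lowest positive value, a pseudocount of 0.0653 (the 10th percentile), features with no missing value, the array number as a replicate block, arrays that share deviations over 0.5 as a random block, an intensity trend with robust variances, array weights, a rank-sum test, each array left out, camera with an estimated correlation, and fry. Averaging adjacent arrays, using them as a random block, taking 1 array of each pair, and leaving out arrays 9 and 10 were added after the structure of the arrays had been seen in the data. Array numbers were checked for pairing across the groups by the correlation of deviations from the group means. They were to count as paired only if this was over 0.1 for every number.

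The fits were tested on simulated data, in which 200 of the 3287 features were changed by 2- or 4-fold between hcf145 and WT, with the measured means and spreads. With independent arrays, limma on 20 arrays recovered 64% of the 2-fold and 96% of the 4-fold changes, and 8.57% of the calls were false. With adjacent arrays correlated as measured, 28.2% of the calls on 20 arrays were false, against 2.33% with adjacent arrays averaged. The averaged fit recovered 41% of the 2-fold and 85% of the 4-fold changes. The simulated noise was drawn separately for each feature, while the real arrays share deviations across features. The share of false calls also depends on how many features change, so these shares do not carry over to the calls below.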

Results

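Transcript levels were measured on arrays in Arabidopsis thaliana of the ecotype Wassilevskija, in wild-type plants (WT) and in plants labelled hcf145, a mutant that the labels describe as defective in building photosystem I, the light-driven complex that reduces ferredoxin in the thylakoid membrane. Each group had 10 arrays, numbered 1 to 10. Every array held 3439 features, of which 692 were paired with 1 gene, 870 with several and 1877 with none, and genes are named below only from features with 1 gene. The deposited intensities summed to between 3319 and 3640 per array, and the number of exact zeros ran from 125 to 150 on the WT arrays and from 120 to 248 on the hcf145 arrays. The precision of every value below is limited by the number of arrays, and the labels do not say which arrays came from separate plants, so the p-values measure only the spread between these arrays, which may be technical.

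Adjacent array numbers shared their deviations. For 20 of 20 arrays, the array whose deviations from the group mean it resembled most within its group was the adjacent number (1 with 2, 3 with 4, and so on), and the consensus correlation of adjacent arrays was 0.661. The 20 arrays therefore held 5 such pairs per group, and p-values that count all 20 separately are too small. Standard errors from the 20 arrays tend to be too small as well. Calls are given below for the 20 arrays, with the call from the 5 against 5 averages of adjacent arrays beside them.

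The mutated gene could not be checked. HCF145 (AT5G08720) was the sole gene of 0 features, and so was CHLH (AT5G13630), the magnesium chelatase subunit also known as GUN5. The titles and descriptions of the mutant samples name hcf145, while their source names give gun5, a different mutant. The group is called hcf145 here after the titles, and every direction below is that of the samples so labelled.

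The comparison of hcf145 with WT asks which transcripts differ in a mutant described as defective in photosystem I assembly. Photosynthesis genes that passed the test were lower in hcf145. PSAN (AT5G64040), a photosystem I subunit on the lumenal side, fell from an intensity of 2.75 ± 0.467 in WT to 1.34 ± 0.203 in hcf145 (SD, n = 10 each), a log2 fold change of -0.95 ± 0.12 (SE; limma adjusted p = 4.62e-06), and every hcf145 array lay below every WT array. PYG7 (AT1G22700), a thylakoid protein needed for photosystem I to accumulate, fell from 0.923 ± 0.137 to 0.268 ± 0.128 (SD, n = 10 each), a 3.51-fold difference (log2 fold change -1.81 ± 0.39 SE, limma adjusted p = 0.00168), again without overlap between the groups. LHCB1.5 (AT2G34420), a chlorophyll-binding antenna protein of photosystem II, fell from 17.7 ± 8.73 to 7.40 ± 2.67 (SD, n = 10 each; log2 fold change -1.19 ± 0.28 SE, limma adjusted p = 0.00285). With adjacent arrays averaged, PSAN and PYG7 stayed past the threshold (limma adjusted p = 0.0197 and 0.0246) and LHCB1.5 did not (limma adjusted p = 0.0840). LHCB1.5 belongs to a family of nearly identical genes, so its value is uncertain as that of 1 gene. PYG7 was not past the threshold with adjacent arrays as a random block (limma adjusted p = 0.0824), nor averaged without arrays 9 and 10 (limma adjusted p = 0.0609), nor with the first array of each pair alone (limma adjusted p = 0.120). It was lowest on hcf145 arrays 7 and 10, at -4.95 and -3.79 on the normalised log2 scale. Leaving 1 array out, its log2 fold change ran from -1.92 to -1.49.

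**Figure D1:**
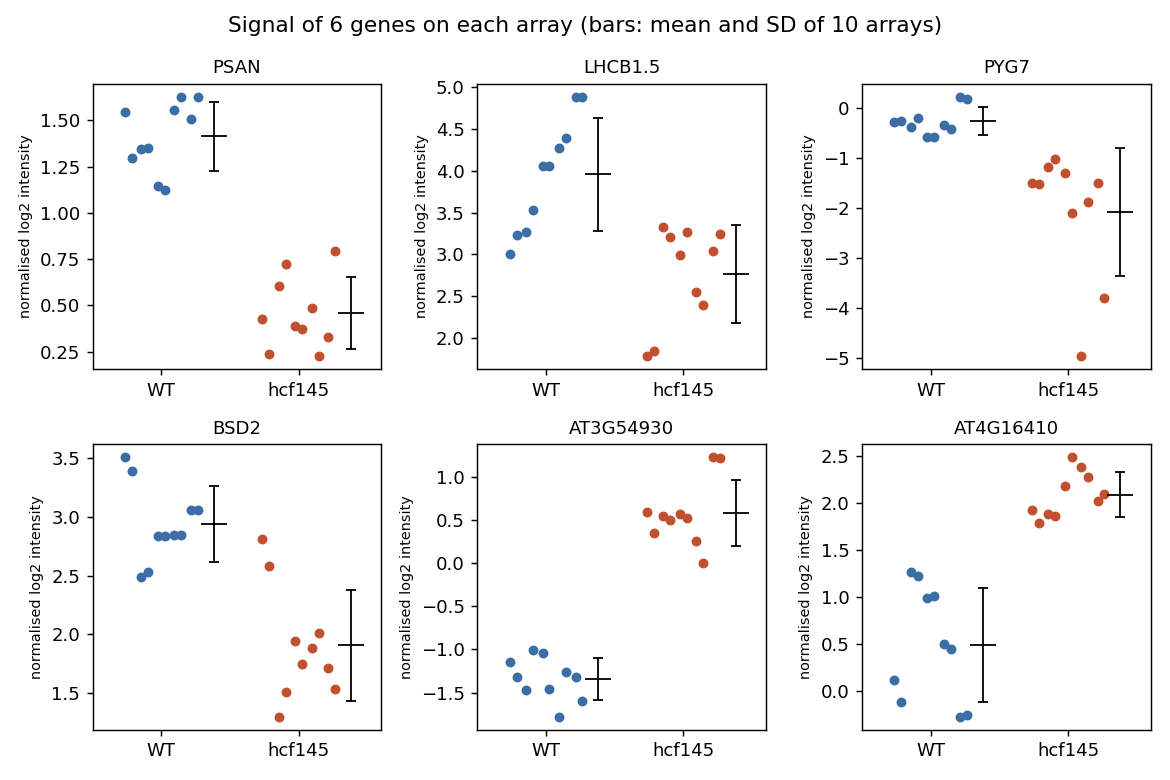
Normalised log2 intensity (vertical axes) of 6 genes on each of the 10 WT and 10 hcf145 arrays, with neighbouring points for adjacent array numbers and bars for the mean and SD of each group. PSAN, PYG7, AT3G54930 and AT4G16410 had no overlap between the groups, while LHCB1.5 and BSD2 overlapped.

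Across all features, 956 of the 3287 tested passed an adjusted p under 0.05 in limma, 433 higher and 523 lower in hcf145, and 333 of them changed at least 2-fold. With adjacent arrays averaged, 243 passed, 117 higher and 126 lower, and all 243 were among the 956. Leaving 1 of the 5 averaged pairs out gave 113 features without arrays 1 and 2, 55 without 3 and 4, 30 without 5 and 6, 27 without 7 and 8, and 319 without 9 and 10. The direction depended on the scaling: in the values as deposited the median feature differed by -0.32 on the log2 scale, against -0.05 after quantile normalisation, and 20.7% of the called features were higher in hcf145 instead of 45.3% (244 higher and 935 lower). Changes are therefore given relative to the quantile-normalised arrays. Of the 956 features, 768 had the same direction in all 5 pairs of array numbers. This agreement is partly built in, because the 956 were called on the same arrays. The groups did not overlap at all for 139 features on the 20 arrays. In the averaged arrays they did not overlap for 321 of the 3131 features with all 10 averages. Random splits of 5 against 5 give 0.794% of features on average. Features share deviations, so a single random split may lie far from this average. Of the called features, 207 had 1 gene (96 higher, 111 lower), and in the averaged arrays 49 had 1 gene (26 higher, 23 lower).

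Among the 12 named genes with the largest rises, 10 also passed with adjacent arrays averaged. AT2G01400 rose most, from 0.138 ± 0.0698 to 0.478 ± 0.0901 (SD, n = 10 each), a 4.91-fold difference (log2 fold change 2.29 ± 0.27 SE, limma adjusted p = 2.65e-06). AT3G54930, which encodes a regulatory subunit of protein phosphatase PP2A, rose 3.80-fold (log2 fold change 1.92 ± 0.16 SE, limma adjusted p = 3.76e-08). With adjacent arrays averaged, the SEs of AT2G01400 and AT3G54930 were 0.36 and 0.23 (limma adjusted p = 0.00544 and 0.00140). AT4G33760, an organellar aminoacyl-tRNA synthetase, rose 3.16-fold, and AGL54 (AT5G27090), a MADS-box transcription factor, rose 3.11-fold. AT4G16410 rose from 1.54 ± 0.622 to 4.28 ± 0.580 (SD, n = 10 each), and AT3G04500 rose 2.98-fold. AT1G05860, CKS (AT1G53000, an enzyme that activates the sugar Kdo for cell wall pectin), AT5G47030 (a subunit of the mitochondrial ATP synthase) and AT1G51350 rose by 1.48 to 1.55 on the log2 scale. AT1G05860 (intensity 0.0692 in WT and 0.124 in hcf145) and CKS (0.0530 and 0.101) were dim, near the 10th percentile of all values (0.0653). Their fold changes are therefore less certain, and as deposited they were 1.13 and 1.07 on the log2 scale. Of these rises, AT2G01400, AT3G54930, AT4G33760, AT4G16410 and AT3G04500 had no overlap between the groups. AT5G19150 (log2 fold change 1.38 ± 0.42 SE) and FBL17 (AT3G54650, an F-box protein of the cell cycle; 1.37 ± 0.50 SE) passed with the 20 arrays counted separately but not averaged, and in the values as deposited neither passed (limma adjusted p = 0.111 and 0.145). FBL17 did pass in the averages without arrays 9 and 10 (1.44, limma adjusted p = 0.0169). The difference of AT5G19150 was -0.04 when its 2 zeros in hcf145 were set to the lowest positive value of the array.

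Among the 12 largest falls, 5 also passed with adjacent arrays averaged: PYG7, AT5G01960, AT4G14330, AT4G31470 and AT3G20490. AT4G31470, which encodes a member of the pathogenesis-related 1-like protein family, was the most even of them. It fell from 3.36 ± 0.736 to 1.12 ± 0.233 (SD, n = 10 each), a log2 fold change of -1.50 ± 0.13 (SE, limma adjusted p = 4.60e-08). With adjacent arrays averaged, its SE was 0.21 (limma adjusted p = 0.00338). AT4G14330, a kinesin of the dividing cell's phragmoplast, fell by 1.51 on the log2 scale, and AT5G01960 by 1.61, while AT3G20490 fell 2.64-fold. The largest fall was that of AT3G56330 (log2 fold change -2.28 ± 0.64 SE, limma adjusted p = 0.0116). Its size rested in part on hcf145 array 1, at -7.47 on the normalised log2 scale, and without that array the fold change was -1.69. The value on the adjacent hcf145 array 2 was a zero and was set missing, so leaving array 1 out removed this pair. On hcf145 array 10 the gene was at -5.10. PYG7 also moved with single arrays, from -1.92 to -1.49 leaving 1 array out. AT3G56330 did not pass with adjacent arrays averaged. Nor did the falls of AT1G53260, AT5G22620, AT5G61470, AT5G15280, AT2G23160 and AT1G58230, which lay between -1.74 and -1.28 on the log2 scale. AT5G15280 encodes a pentatricopeptide repeat protein, a class that binds organellar RNA.

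The gene lists fixed before the data were examined were thinly covered. A member counts as measured here if it was the sole gene of a tested feature. Of 12 photosystem I subunits, 1 was measured (PSAN, lower; 1 of 1 adjusted over the list alone), and of 8 photosystem I assembly and iron-sulfur factors, 1 was measured (PYG7, lower; 1 of 1 adjusted over the list alone). Of 15 members of light-harvesting complex II, 1 was measured (LHCB1.5, lower, 1 of 1 adjusted over the list alone). Where a list had 1 measured member, adjustment over the list alone left its p-value unadjusted. Of 3 measured photosystem II subunits none passed in limma, 0 also adjusted over the list alone, with log2 fold changes of 0.28 ± 0.12 for PSBY, -0.45 ± 0.23 for PSBW and -0.49 ± 0.29 for PSB27 (SE); PSBY had an unadjusted p of 0.0265, and as deposited it was at 0.16. The list's shift was not past the threshold in camera (median -0.45, adjusted p = 0.823, or 0.809 with an estimated correlation). Its size depended on the scaling, and with median centring the list's median was -0.05. Of 2 Calvin cycle enzymes, neither passed (SBPASE -0.43 ± 0.19 SE, limma adjusted p = 0.0893; PRK 0.17 ± 0.17 SE), and 0 did adjusted over the list alone. As deposited SBPASE was at -0.71 and past the threshold (limma adjusted p = 0.0117), and PRK was at -0.02. Of 2 enzymes of chlorophyll synthesis, CHLP (AT1G74470), which makes the phytyl tail of chlorophyll, fell by 0.60 on the log2 scale (limma adjusted p = 0.0454), a call that ended with adjacent arrays averaged and in 14 of the 20 fits that left 1 array out. Without arrays 9 and 10 of both groups, the log2 fold change of CHLP was -0.28 and past the threshold (limma adjusted p = 0.0433). With median centring on all arrays it was -0.32 and not past the threshold (limma adjusted p = 0.339). CHLM had a log2 fold change of -0.39 ± 0.19 (SE) and was not past the threshold over all features (limma adjusted p = 0.119); 2 of 2 passed adjusted over the list alone, and in the values as deposited CHLM was at -0.78 (limma adjusted p = 0.00256). PRXIIE, the 1 measured antioxidant gene, had a log2 fold change of -0.47 ± 0.18 (SE) and did not pass (limma adjusted p = 0.0571, unadjusted limma p = 0.0175). It passed over the list alone only because 1 member leaves the p-value unadjusted. As deposited it was at -0.67 (limma adjusted p = 0.0105).

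Of 5 measured plastid ribosomal protein genes, 2 rose and 3 did not pass, and adjusted over the list alone 2 rose. PRPL34 (AT1G29070) rose 2.09-fold (log2 fold change 1.06 ± 0.25 SE, limma adjusted p = 0.00349) and PRPL5 (AT4G01310) rose 1.39-fold (0.47 ± 0.17 SE, limma adjusted p = 0.0421), and neither call held with adjacent arrays averaged, nor in the values as deposited (0.68 and 0.18, limma adjusted p = 0.0716 and 0.497). PRPS10, PRPS6 and PRPL17 had log2 fold changes of 0.28, 0.07 and -0.15; as deposited PRPL17 was at -0.39 (limma adjusted p = 0.0454). As a set, the list did not pass in camera (median 0.28, adjusted p = 0.554; adjusted p = 0.441 with an estimated correlation), and its median was 0.03 in the values as deposited. Of the other 10 lists, no member was the sole gene of a tested feature. These were light-harvesting complex I, electron transport and ATP synthase, plastid transcription and RNA metabolism, plastid chaperones and proteases, and isoprenoid and carotenoid synthesis. The rest were starch metabolism, plastid protein import, photorespiration, mitochondrial respiration, and markers of other tissues and cell types. Members may lie on features with several genes or on features left out.

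**Figure D2:**
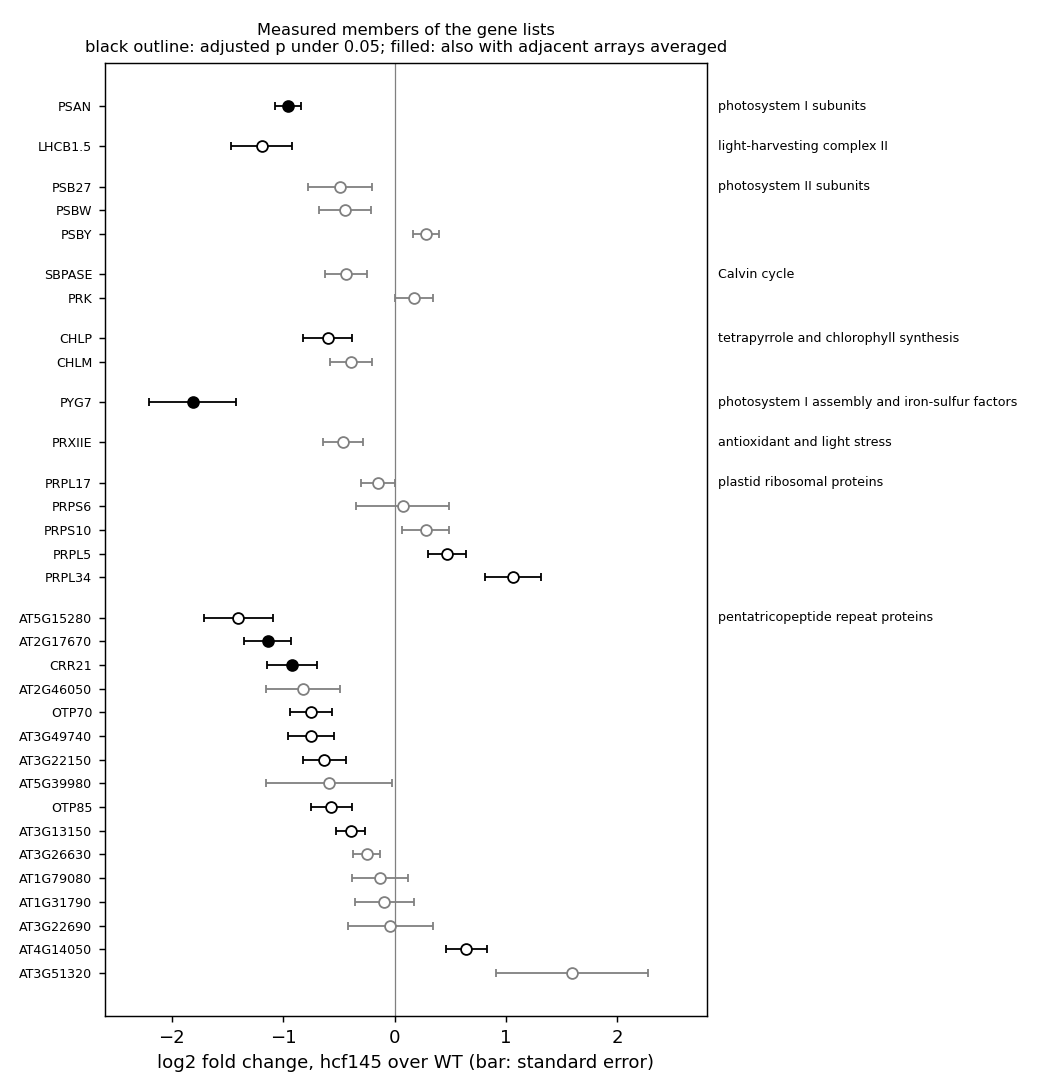
Log2 fold change of hcf145 over WT (horizontal axis, bars for the standard error) for each measured member of the 8 lists fixed beforehand that had any and of the pentatricopeptide repeat list, with black outlines for adjusted p under 0.05 in the 20 arrays and filled points where the averaged arrays passed too. Of the genes shown, PSAN, PYG7, AT2G17670 and CRR21 are filled, and all 4 lie below 0. The pentatricopeptide repeat list was added after the gene names were read.

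The arrays separated by group along the first principal component, which held 23.9% of the variance of the 2784 features measured on all arrays. All WT arrays had negative and all hcf145 arrays positive scores. The second component (18.3%) set arrays 9 and 10 of both groups apart from the rest, and without those arrays 1070 features passed in place of 956. Arrays of the same number also had positively correlated deviations across the groups (0.07 to 0.36), so pairing by number stays open. With number as a block, the averaged arrays gave 500 features in place of 243. The calls given here are from fits without this block unless it is named. The brightest features took a larger share of the signal in hcf145: the 10 brightest held 18.7 ± 1.87% of the total per array against 12.6 ± 0.926% in WT (SD, n = 10 each).

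**Figure D3:**
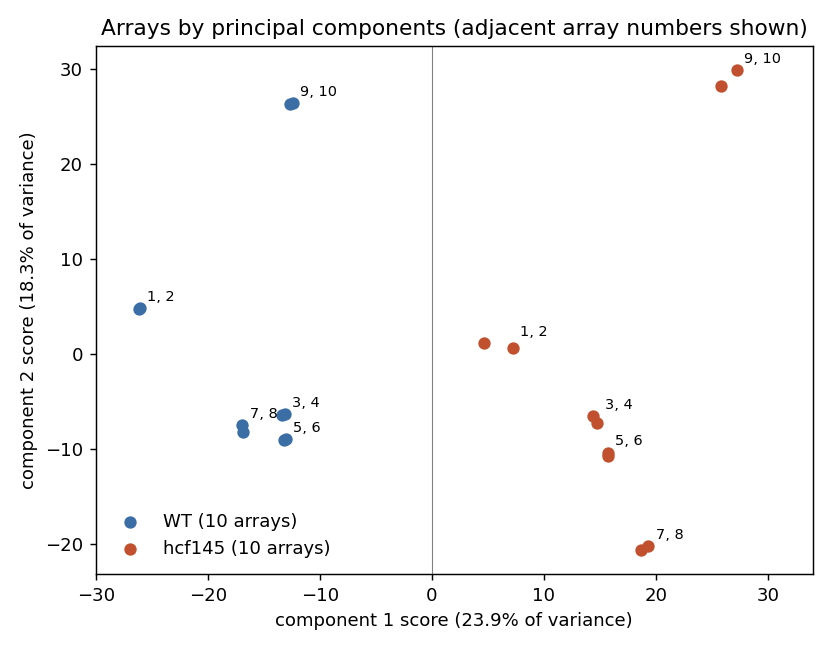
Scores of the 20 arrays on the first 2 principal components (23.9% and 18.3% of the variance), in blue for WT and red for hcf145, with each pair of adjacent array numbers marked. The groups lie on either side of 0 on the first component, adjacent numbers lie together, and arrays 9 and 10 of both groups lie highest on the second.

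Values of 5 features reached the maximum of the scale, 100, on at least 1 hcf145 array, and no WT value did. AT4G31530 stood at the maximum on all 10 hcf145 arrays, against 69.4 ± 17.9 in WT (SD, n = 10), so its level in hcf145 is only bounded. In the values as deposited the log2 fold change was at least 0.58, and no p is given, because the cap removes the spread in hcf145. After normalisation it was 0.13, which decides nothing. Quantile normalisation gives equal ranks the same value on every array, so a feature near the top rank in both groups can change little. AT4G31530 is named because it was saturated, which was seen only in the values.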

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

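The tests of the scaling between arrays and of features of like brightness were chosen after their results or related values had been seen; the averages of adjacent arrays, the splits that keep them together and the fits without arrays 9 and 10 were also added after the data had been seen. The test of brightness replaced 1 planned on the normalised values (0.0599), which decides nothing because normalisation holds such medians near 0.

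Single arrays lay far from the other measured arrays of their group for 8 named genes, in 9 of the 90 groups of arrays tested. Chance gives about 5% of groups if arrays are independent, but adjacent arrays shared deviations, so this rate need not hold. A pair that deviates together can also escape the rule. CHLP was not flagged in hcf145, where it stood at 0.36 and 0.05 on arrays 9 and 10. In WT, AT5G47030 stood at -5.98 on the normalised log2 scale on array 8 (others -3.45 to -2.15), AT5G19150 at -6.79 on array 2 (others -3.99 to -2.87), FBL17 at -5.72 on array 9 (others -3.56 to -2.42) and AT5G22620 at -0.74 on array 2 (others -2.05 to -1.38). In hcf145, AT3G04500 stood at -1.10 on array 2 (others -0.49 to 0.21), FBL17 at -5.25 on array 10 (others -2.17 to -0.55), AT2G23160 at -5.87 on array 7 (others -3.22 to -1.51), SBPASE at -2.15 on array 4 (others -1.38 to -0.61) and GH9B12 at -1.57 on array 1 (others -3.35 to -2.40).

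In 100 splits of the 20 arrays into 10 and 10, only the real 1 gave 956 features, and the highest of the others gave 8. In 100 splits of the 10 averaged arrays into 5 and 5, only the real 1 gave 243, and the highest of the others gave 1. A count this large was thus rare among the splits, but 100 splits do not exclude chance. Nor can splits separate the genotype from other differences between the groups. Splits of the 20 arrays part adjacent arrays that the real split keeps together. In 100 splits that keep them together, only the real 1 gave 956, which does not exclude chance either. The highest of the others gave 644. That split differed from the real 1 by exchanging WT arrays 9 and 10 with hcf145 arrays 1 and 2. Of the 99 other such splits, 12 called over 100 features. Those that called 453, 383, 306 and 285 likewise exchanged 1 pair of each group. Such splits keep most of the real grouping, so their counts are not free of the real difference.

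Of 3 technical explanations for the fall of PSAN and PYG7, scaling would have to bring either gene near 0, but the highest log2 fold change of the pair over the 4 scalings was -0.74 (PSAN, centred on features outside the lists). A shift shared by features of like brightness would need their median to come close to each gene's own change, whereas in the values as deposited the median of the 200 nearest in brightness was at most 0.191 of the gene's change (PYG7). Single features of like brightness did vary: PYG7 ranked 1 from the lowest among its neighbours and PSAN 19. Without arrays 9 and 10 of both groups the higher of the 2 values was -0.906 (PSAN). A lower transcript level in the mutant remains as a hypothesis, not tested further; which mutant the plants carry stays open.

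The gap between 956 calls on 20 arrays and 243 on averaged arrays was weighed against 2 explanations. If adjacent arrays were as independent as any others, averaging them would lower the median residual SD to 0.707 of its value, but it fell only to 0.922, which argues against this. That adjacent arrays are repeat readings of 1 hybridisation could not be decided by the test chosen for it: odd against even numbers within a group gave 0 features, as this explanation needs, but the splits that kept adjacent arrays together had medians of 0 in WT and 0.5 in hcf145 (highest 467 and 132), so the bound written beforehand was met by a tie at 0. Repeat readings and separate plants handled together cannot be told apart here, because no label describes the arrays.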

How the results depend on the processing

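Averaging adjacent arrays, the random block of adjacent arrays, single arrays of each pair and the fits without arrays 9 and 10 were chosen after seeing the data. The counts of called features stayed within 1.5 times under the alternatives set beforehand, from 686 with correlated arrays as a random block to 1239 with the replicate block, but for the following. In the values as deposited 244 features were higher and 935 lower, with 20.7% higher. The share higher was 50.7% with median centring and with centring outside the lists, and 49.0% with zeros at the lowest value. The pseudocount left 187 features changed at least 2-fold, which follows from its shrinking of small values. Leaving out each array in turn gave 816 to 987 features (377 to 449 higher, 439 to 538 lower, 295 to 358 at least 2-fold, 44.3% to 46.6% higher).

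Adjacent arrays as a random block gave 425 features (217 higher, 208 lower, 51.1% higher; 214 at least 2-fold). Averaged, 5 against 5, they gave 243 (117 higher, 126 lower; 187 at least 2-fold), and without arrays 9 and 10 319 (143 higher, 176 lower; 194 at least 2-fold). The first array of each pair gave 151 (84 higher, 67 lower, 55.6% higher; 132 at least 2-fold) and the second 141 (79 higher, 62 lower, 56.0% higher; 121 at least 2-fold), each from 10 arrays in place of 20. Apart from the fewer arrays, the causes were not tested.

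Array numbers failed the rule for pairing: the correlation of deviations within a number was under 0.1 for 3 and 4. It was positive throughout (0.07 to 0.36), and 14 of 20 arrays were nearest to their own number in the other group. Pairing stays open. With the replicate block 1239 features passed, and in the averaged arrays the replicate block gave 500 (251 higher, 249 lower, 50.2% higher). On single arrays the block changed the calls of 2 named genes, PRPL5 (lost) and PRXIIE (gained), and of the pentatricopeptide repeat list (adjusted p = 0.0291), and no other. On averaged arrays, whose correlations ran from 0.0533 to 0.444, it added 7 named genes and lost 0: LHCB1.5 (adjusted p = 0.0351), PRPL34 (0.0301), GLDH (0.0478), AT5G22620 (0.0391), AT5G61470 (0.0416), AT5G15280 (0.0306) and AT1G58230 (0.0263), and this list (0.0479).

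Of the 41 named genes, 38 passed on 20 arrays and 18 of these with adjacent arrays averaged. Over 475 values of named genes under the alternatives set beforehand other than leaving 1 array out, 429 kept direction and side of the threshold, 34 fell short of it and 11 newly passed; 1 reversed, AT5G19150 at -0.0377 with zeros at the lowest value, which replaces its 2 missing values. Leaving 1 array out, 755 of 820 stayed, 59 fell short and 6 newly passed, and under the settings added later 160 of 287 stayed, 126 fell short and 1 newly passed. Leaving 1 array out ended the calls of CHLP, FBL17 and PRPL5 in 14 of 20 fits each, of GH9B12 in 13 and of AT1G53260 in 4. In fry, which does not compare a list with other genes, 7 of 10 lists passed (adjusted p = 1.06e-05 to 0.0343), among them the plastid ribosomal list (0.28; adjusted p = 0.0264), which passed in no camera setting; with adjacent arrays averaged 3 of 10 passed (thylakoid complexes, pentatricopeptide repeat proteins and pooled photosynthesis, each 0.00991) and the plastid ribosomal list did not (0.147). Medians of uncalled lists near 0 changed sign: thylakoid complexes were at 0.0128 without arrays 9 and 10, and assembly factors at 0.0315 averaged without them and 0.0401 with first arrays. Housekeeping genes were at -0.215 as deposited, -0.0417 with correlated arrays as a block, -0.0427 with second arrays, and -0.0722 to 0.118 leaving 1 array out. Floral regulators were at 0.0635 with median centring, 0.0637 with centring outside the lists, 0.0102 with zeros at the lowest value, 0.00967 with the pseudocount, 0.00295 with correlated arrays as a block, 0.0805 without arrays 9 and 10 with or without averaging, and -0.0594 to 0.0355 leaving 1 array out. The cause was not tested. Using the mean of a gene's features moved nothing, since the 1 gene with 2 features is in no list. Signal over background could not be assessed, because the deposited values carry no background.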

Other observations

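The lists below were written after the gene names had been read and before any difference was computed; the test against random lists was planned before its result was seen.

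Genes of pentatricopeptide repeat proteins, which bind and process RNA in chloroplasts and mitochondria, tended to lie lower in hcf145. Of 16 measured, 8 fell, 1 rose and 7 did not pass on 20 arrays, and 14 of the 16 had a log2 fold change below 0 (median -0.58). AT5G15280 fell 2.64-fold. On the log2 scale AT2G17670 fell by 1.14, CRR21, an editing factor for a plastid NDH transcript, by 0.92, OTP70 by 0.75 and OTP85 by 0.57, while AT4G14050 rose by 0.64 (0.39 without arrays 9 and 10; as deposited 0.52, adjusted p = 0.0531). CRR21, OTP70 and OTP85 were chosen after their values were seen, as were NDHS and NDHN below. With adjacent arrays averaged, 2 of the 16 passed, AT2G17670 and CRR21. In camera the list did not pass (adjusted p = 0.0868; adjusted p = 0.161 with an estimated correlation; 0.0291 to 0.229 over 39 alternatives, of which 2 passed, the replicate block on single and on averaged arrays). In fry, which does not compare the list with other genes, its adjusted p was 1.06e-05 (0.00991 with adjacent arrays averaged). The hypothesis that features of like brightness fall as often was tested with 10000 random lists matched on mean log2 value. The list's median lay at percentile 0.23 of theirs (their median was -0.04). The values were normalised, which holds medians of features of like brightness near 0, so the test cannot decide this for the values as deposited. It shows only that after normalisation the list lay lower than most such lists. A shared fall of these genes stays open: the list did not pass against other genes in the main camera fit, and the arrays share deviations in pairs. No biological cause was tested.

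BSD2 (AT3G47650), a chaperone needed to assemble Rubisco, fell 2.05-fold, to an intensity of 3.90 ± 1.48 in hcf145 (SD, n = 10; log2 fold change -1.04 ± 0.19 SE, limma adjusted p = 0.000354), and passed with adjacent arrays averaged (adjusted p = 0.0448; 4.4e-05 to 0.0808 over 39 alternatives). With PYG7 it made 2 of 8 measured assembly factors that fell, while LPA19, CCS1, CRR41, PAC, ATAB2 and CCB3 did not pass (camera adjusted p = 0.554 for the list). Among 9 genes of thylakoid complexes, PSAN and LHCB1.5 fell, and the NDH subunits NDHS and NDHN had log2 fold changes of -0.02 and -0.26 without passing (camera adjusted p = 0.328). All 9 photosynthesis genes of the fixed lists together had a median of -0.45, with 3 lower, none higher and 6 not past the threshold (camera adjusted p = 0.124, or 0.350 with an estimated correlation). Over 40 alternatives their median ran from -0.668 to -0.316. Among 7 redox genes, NADP-MDH (AT5G58330), which exports reducing power from the chloroplast as malate, rose 1.64-fold and GLDH (AT3G47930), the last enzyme of ascorbate synthesis, rose 1.54-fold; neither passed with adjacent arrays averaged (camera adjusted p = 0.554 for the list), and as deposited GLDH had a log2 fold change of 0.34 and did not pass (adjusted p = 0.107).

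Of 9 housekeeping genes 1 rose (IYO, log2 fold change 0.57; not with adjacent arrays averaged, adjusted p = 0.139, nor as deposited, where it was 0.30 with adjusted p = 0.0954), in a list with a median of 0.06 (camera adjusted p = 0.675). Of 6 genes listed as floral and meristem regulators, AGL54 rose and AGL26 fell by 0.60 on the log2 scale (0.92 as deposited). The list was written from gene names, and a role of either gene in flowers or meristems was not tested. With adjacent arrays averaged AGL54 passed and AGL26 did not (limma adjusted p = 0.133). The list's median was -0.01 and its mean 0.21, so these differ in sign, and camera took the list as higher (adjusted p = 0.823). Of 4 glycosyl hydrolases of family 9, which cut cellulose-like glucans, GH9B11 and GH9B12 fell by 0.89 and 0.56 on the log2 scale (GH9B12 by 0.95 as deposited), neither with adjacent arrays averaged (camera adjusted p = 0.554).

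In the values as deposited, the median log2 difference was -0.37, -0.47, -0.43 and -0.22 in the first 4 pairs of array numbers and 0.07 in arrays 9 and 10. It was -0.25 for the brighter and -0.40 for the dimmer features. It was -0.28 with all arrays scaled to 1 mean, and -0.17 with the 10 brightest features of each array left out of that mean. Feature 1803, which is paired with 2 genes and was singled out because it reached the maximum on 5 hcf145 arrays, stood at 24.4 ± 10.9 in WT (SD, n = 10) and at a mean of at least 89.1 in hcf145. The cap narrows the spread in hcf145, so no p is given; the groups did not overlap.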
